A study of Homo sapiens with 4 samples.

How the data were processed

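The data were expression profiles of H358, an established human lung adenocarcinoma cell line, measured on 4 Illumina human BeadChips, 1-colour arrays on which each probe is read from many beads. Per the labels, 2 arrays held RNA from cells given a scrambled control shRNA and 2 held RNA from cells given an shRNA against ADAR, the enzyme that converts adenosine to inosine in double-stranded RNA. An shRNA is a short hairpin RNA that directs the degradation of a matching transcript. The series design calls the replicates of each group biological, but does not state whether they came from separate cultures. The p-values therefore rest on 2 samples per group, which limits their precision. Each combines the gene's own spread with a variance shared over all genes, which carried more weight (6.83 prior against 2 residual degrees of freedom).

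The deposited table from the scanner held 47322 probes, each with a mean signal intensity on a linear scale, a bead number, a bead standard error and a detection p-value, per the file headers. The deposited detection p-value compares a probe with the array's negative controls, and a small value means a signal above background. GenomeStudio produced the values, per the submitters' processing notes, and its version was not given. The authors also deposited a table of processed intensity values for the same probes. Its columns had medians of 8.05, 8.04, 8.02 and 8.03 on a linear scale, about 25.1% to 25.2% of values lay below 0, and each column ranked the probes as the raw signal of its array did (Spearman's rho of 1 over probes). The normalization behind it was not given in the sources used here, so it served only as an alternative.

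The raw intensities were background corrected with the normexp model of limma 3.58.1 in R 4.3.3, with the background estimated from the detection p-values and an offset of 16, then quantile normalized and put on the log2 scale. A probe entered the tests if its detection p was under 0.05 on at least 2 of the 4 arrays. Gene names came from the platform annotation. It gave 1 symbol for 30113 probes and several for 8, and it did not list 17201 probes, which are unnamed here. Of the single-symbol probes, 30074 had an Entrez identifier in the current gene table, assembly GRCh38.p14, and 0 symbols needed updating. The filter kept 21263 probes, of which 16268 were named, and each gene was represented by its brightest probe over all 4 arrays, which left 12197 genes. Genes outside the annotation used were not analysed here.

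Groups were compared with limma's lmFit and eBayes, which had 2 residual and 6.83 prior degrees of freedom, with no replicate block. The test was 2-sided, and a gene was said to rise, fall or change at a Benjamini-Hochberg adjusted p under 0.05. Every log2 change is ADAR shRNA minus scrambled, with its moderated standard error (SE). A gene with no probe detected on either array of a group has only a bound there. Its fold is given as "at least", and compares the mean of the brighter group with the mean, over the dim arrays, of the higher of the lowest detected probe's value and the gene's own value. For a named gene detected on 1 of the 2 dim arrays the same bound is given, in place of the log2 change or beside it.

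The comparison, its test, 29 gene lists and the rule for naming genes were fixed before the data were examined. Lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 29 lists, and again with an estimated correlation. Members that passed were counted with adjustment over all genes and adjusted over the list alone. The rule named ADAR, the 10 largest rises and 10 largest falls by fitted log2 change among changed genes whose groups did not overlap, up to 2 rises and 2 falls per list, the other RNA-editing enzymes, and PTK2, the gene of focal adhesion kinase. Lists of haematopoietic, fibroblast and endothelial, and alveolar and airway markers served as a check for other cells, although H358 is itself a lung line.

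The replicates of a group were checked for duplication. After scaling, 26.6% of probes on the scrambled pair and 18.6% on the ADAR shRNA pair differed by more than bead error allowed, where chance gives 5%, so the arrays of a pair were not 1 set of readings deposited again. Repeat arrays of 1 RNA would differ in this way too, and the arrays were counted as separate samples because the labels list them so. On simulated arrays with 12197 genes, of which 200 were changed, the fit recovered 28% of changes of 1 log2 unit and 98% of changes of 2. It called 8 unchanged genes and gave 0 wrong directions. In the data 57.8% of genes changed, which makes the Benjamini-Hochberg cut-off more lenient. These rates therefore do not describe the comparison itself. In a separate simulation only 1 list was shifted and no other gene was changed. Camera called that list at the preset correlation and did not call it with an estimated one. Simulated genes were drawn independently of each other, so the preset call was not tested on lists whose genes vary together. Nor was it tested against a background in which many other genes change, as in the data.

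Alternatives covered the replicate block, the background correction and its offset, cyclic loess, median scaling, the authors' processed intensities, the filter on detection, the probe taken per gene, the variance model, array weights, each replicate left out, the threshold and the set test. Background correction with no normalization between the arrays was added after the data were seen.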

Results

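The series profiled gene expression in H358 lung adenocarcinoma cells with and without knockdown of ADAR, to find which transcripts differ between them. There were 2 arrays of cells given scrambled shRNA and 2 of cells given ADAR shRNA. Probes detected above background numbered 20901 and 20031 on the scrambled arrays, and 18722 and 19294 on the ADAR shRNA arrays. The upper quartile of the raw signal was 143 and 115 on the scrambled arrays against 94.5 and 92.1 on the ADAR shRNA arrays. Over 12197 genes, normalized values correlated at 0.984 between the scrambled arrays and 0.987 between the ADAR shRNA arrays, against 0.765 to 0.795 across groups; genes are not independent replicates.

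ADAR itself, the targeted gene, fell by 1.03 on the log2 scale (SE 0.21, adjusted p = 0.00292). Its brightest probe, ILMN_1776777, averaged 11.06 ± 0.25 (SD, n = 2) in scrambled cells and 10.03 ± 0.22 (SD, n = 2) in ADAR shRNA cells. The raw signals of that probe were 2703 and 2676 on the scrambled arrays and 755 and 932 on the ADAR shRNA arrays. The other detected ADAR probe, ILMN_2320964, read 9.38 and 8.83 in scrambled cells and 8.74 and 9.10 in ADAR shRNA cells, a difference of -0.19 (SE 0.25, adjusted p = 0.557). That probe passed under median scaling, where it fell by 0.90 (adjusted p = 0.0397), and with no normalization between arrays, where it fell by 1.04 (adjusted p = 0.0329). Of the 12197 genes, 2172 (17.8%) had a log2 difference as low as that of ADAR or lower.

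Among the other RNA-editing enzymes, ADARB1, a second adenosine deaminase acting on RNA, rose by 1.89 (SE 0.19, adjusted p = 4.08e-05), and the tRNA deaminase ADAT2 rose by 0.75 (SE 0.21, fitted). The tRNA deaminases ADAT1 and ADAT3 fell by 1.07 (SE 0.23) and fell by 0.89 (SE 0.18). Of the cytidine deaminases, APOBEC3B fell at least 2.55-fold and was undetected in ADAR shRNA cells, APOBEC3C fell by 0.58 (SE 0.21) and APOBEC3F fell by 0.77 (SE 0.20). ADAT2 lost its call under median scaling (0.51, adjusted p = 0.0897), with no normalization (0.38), and without scrambled replicate 2 (0.53, adjusted p = 0.0943) or ADAR shRNA replicate 2 (0.67, adjusted p = 0.074). APOBEC3C lost it without scrambled replicate 1, scrambled replicate 2 or ADAR shRNA replicate 2 (-0.66, -0.45 and -0.37, adjusted p = 0.0594, 0.189 and 0.265). It also lost it with no background correction (-0.34, adjusted p = 0.0853), an offset of 50 (-0.35, adjusted p = 0.0767), the authors' values (-0.59, adjusted p = 0.0577), no filter on detection (adjusted p = 0.0782) or a trend and robust variance (adjusted p = 0.0584). APOBEC3F lost its call without scrambled replicate 1 (-0.10, adjusted p = 0.759) or ADAR shRNA replicate 1 (-0.64, adjusted p = 0.0642), and with the mean of all its probes (-0.46, adjusted p = 0.0818), of which the other 2 read -0.67 and 0.064. ADAT2 was detected on 1 of 2 scrambled arrays and rose at least 1.55-fold against background. APOBEC3D differed by -0.05 (SE 0.29, adjusted p = 0.895) and APOBEC3G by 0.09 (SE 0.21, adjusted p = 0.757). In this list 2 of 9 members rose and 5 fell, also adjusted over the list alone, and camera did not call it (adjusted p = 0.723). PTK2, which encodes focal adhesion kinase, fell by 0.95 (SE 0.19, adjusted p = 0.00261), from 10.77 ± 0.20 to 9.82 ± 0.04 (SD, n = 2 per group). The 2172 genes with a log2 difference as low as that of ADAR or lower also lay below PTK2.

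**Figure D1:**
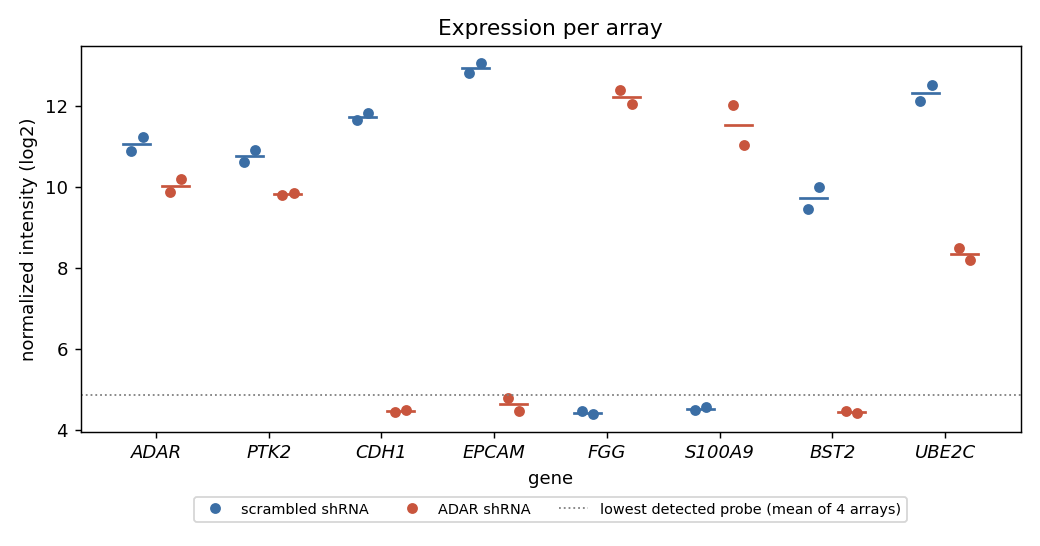
Normalized intensity (log2, vertical axis) of 8 genes on each of the 4 arrays, with scrambled shRNA in blue and ADAR shRNA in red; dots are arrays, short lines are means of 2 arrays and the dotted line is the lowest detected probe. ADAR fell by 1.03 and PTK2 fell by 0.95, while CDH1, EPCAM and BST2 reached the background level with ADAR shRNA, and FGG and S100A9 left it.

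Between the groups 7044 of 12197 genes changed (57.8%), of which 3116 rose and 3928 fell. At least 2-fold changes were seen in 1756 risen and 2237 fallen genes, and at least 16-fold changes in 125 and 83. The 2-fold counts were 1040 and 3977 under median scaling, 893 and 4556 with no normalization between arrays, and 1256 and 1567 with no background correction. The 16-fold counts were 82 and 130, 74 and 150, and 59 and 41 in the same order. FGG, which encodes the fibrinogen gamma chain, rose at least 170-fold (adjusted p = 3.58e-08), and S100A9, a subunit of the calcium-binding protein calprotectin, rose at least 105-fold. The reductase gene AKR1B10 rose by 6.92 (SE 0.78) and its near-identical neighbour AKR1B15, whose probe may share its transcripts, rose by 6.76. QPCT rose by 6.61 (SE 0.57) and TSPAN7 by 6.61 (SE 0.30), ESM1 rose at least 82.9-fold, LCN1 at least 80.4-fold and the laminin gene LAMA1 by 6.26 (SE 0.42), and the serine protease gene HTRA1 rose at least 75.1-fold. The scrambled arrays differed in 4 of these: without scrambled replicate 1 and without scrambled replicate 2, AKR1B10 rose by 8.57 and 5.45, AKR1B15 by 7.499 and 5.97, QPCT by 7.81 and 5.57, and LAMA1 by 6.93 and 5.44. AKR1B15, TSPAN7, ESM1, LCN1 and LAMA1 were detected on 1 of 2 scrambled arrays, and AKR1B15, TSPAN7 and LAMA1 rose at least 100-fold, 92.5-fold and 64-fold against background. Other probes of FGG, TSPAN7, ESM1 and LAMA1 read 5.99, 5.88, 5.67 and 5.15. With a trend and robust variance AKR1B10 did not pass (adjusted p = 0.0572).

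Among the falls, the dehydrogenase gene DHRS2 fell at least 359-fold. LCN2, which encodes lipocalin 2 and was detected on all 4 arrays, fell 372-fold and fell by 8.54 on the log2 scale (SE 0.19), from 14.39 ± 0.01 to 5.85 ± 0.22 (SD, n = 2 per group). EPCAM, an epithelial adhesion molecule, fell at least 260-fold, with other probes at -7.41 and -5.74, and the protease inhibitor SPINT2 fell at least 144-fold. PAGE5 fell at least 180-fold, and the GAGE genes GAGE4, GAGE12G, GAGE12C and GAGE12H fell at least 185-fold, 167-fold, 161-fold and 117-fold; GAGE copies are near-identical, so their probes may not be independent. CRABP2, a retinoic acid binding protein, fell by 7.62 (SE 0.21). Of the risen genes 419 were undetected on both scrambled arrays, and of the fallen genes 908 were undetected on both ADAR shRNA arrays. The split of directions depended on scaling: 44.2% of changed genes rose, against 22.3% under median scaling and 17.6% with no normalization between arrays, where the median of all genes was -0.54 and -0.68 in place of -0.08.

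All 35 measured genes of G2 and mitosis fell, with a median of -2.48 (camera adjusted p = 1.62e-12, and adjusted p = 0.731 with an estimated correlation), and 28 of 30 genes of S phase and DNA replication fell, with a median of -2.09 (camera adjusted p = 5.44e-10, and adjusted p = 0.731 with an estimated correlation). UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, fell by 3.99 (SE 0.21), with another probe at -2.20, and CDC20, an activator of the anaphase-promoting complex, fell by 3.87 (SE 0.25). The replicative helicase subunit MCM4 fell by 4.37 (SE 0.20) and the replication factor GINS2 fell by 3.93 (SE 0.22). Of the other 2, CDC6, chosen after its values were seen, differed by -0.48 (SE 0.28, adjusted p = 0.169), and the transcription factor gene E2F1 rose by 0.48 (SE 0.18, adjusted p = 0.0479). That rise did not pass with cyclic loess (0.47, adjusted p = 0.0516), no background correction (0.25), an offset of 50 (0.26), a trend and robust variance, median scaling (0.23, adjusted p = 0.2905) or no normalization (0.097, adjusted p = 0.715). It did not pass without scrambled replicate 1 or 2 (0.47 and 0.43) or ADAR shRNA replicate 1 or 2 (0.46 and 0.57) either (adjusted p = 0.0879 to 0.164). The counts were equal when adjusted over the list alone. Raw signal was lower on the ADAR shRNA arrays; relative to the median of all genes, the lists lay at -2.46 and -2.16 under median scaling.

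Genes of epithelial junctions and identity fell in 22 of 27 cases and rose in 3, with a median of -1.89, or -1.66 with undetected genes at their bounds (camera adjusted p = 1.42e-06, and adjusted p = 0.731 with an estimated correlation). CDH1, which encodes E-cadherin, fell at least 113-fold, from 11.73 ± 0.13 (SD, n = 2) to a level not above background, and EPCAM was described above. The tight junction gene CLDN1 rose by 3.61 (SE 0.27), and JUP, which encodes plakoglobin, rose by 0.86 (SE 0.23). JUP did not pass under median scaling (0.29, adjusted p = 0.226), with no normalization (0.16), or without scrambled replicate 1 (0.60, adjusted p = 0.0531) or ADAR shRNA replicate 2 (0.75, adjusted p = 0.05825), and under median scaling 22 genes of the list fell and 1 rose. The counts were equal adjusted over the list alone. The call was also lost when detection p had to be under 0.01 on all 4 arrays (adjusted p = 0.381), a filter that removes genes lost from a group.

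Mesenchymal genes moved both ways: 10 of 20 rose and 6 fell, also adjusted over the list alone, and camera did not call the list (adjusted p = 0.429). The secreted glycoprotein gene FSTL1 rose at least 12.5-fold and ACTA2, which encodes smooth muscle actin, rose by 2.67 (SE 0.23). SNAI2, a repressor of E-cadherin, fell at least 18.4-fold, and the matrix gene TNC fell by 2.62 (SE 0.23), and another probe of each read -2.64 and -5.10. The list's median of 0.31 turned to -0.07 under median scaling, where 9 rose and 8 fell. Of 36 focal adhesion genes 8 rose and 15 fell, also adjusted over the list alone (camera adjusted p = 0.442), and 5 rose and 22 fell under median scaling. The kinase gene SRC rose by 1.88 (SE 0.18) and PARVB by 1.86 (SE 0.20), although another PARVB probe read -0.19, while the integrin genes ITGB4 and ITGA3 fell by 3.55 (SE 0.30) and fell by 3.21 (SE 0.20), with another ITGA3 probe at -0.42.

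Among secreted proteases and matrix remodelling genes 4 of 19 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.749). Their median was 0.04, while their mean was -0.63 and the direction of the test was down. The protease inhibitor SERPINE2 rose by 2.99 (SE 0.27) and the cathepsin gene CTSL by 2.56 (SE 0.21), with other CTSL probes at 2.73 and 3.75. MMP9, which encodes a gelatinase, fell at least 36.3-fold and PLAU, which encodes urokinase, fell by 5.28 (SE 0.23). Of 18 TGF-beta target genes 5 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.838). The type IV collagen gene COL4A1, detected on 1 of 2 scrambled arrays, rose at least 17.6-fold and COL4A2 rose at least 5.96-fold (fitted log2 change 2.93, and 3.55 without ADAR shRNA replicate 2), while CCN1 fell by 3.24 (SE 0.24) and PMEPA1 fell by 2.43 (SE 0.22), with other PMEPA1 probes at -2.07 and -1.37. The median of this list was -0.06, its mean 0.14 and its test upward. Under median scaling 4 protease and 5 TGF-beta target genes rose and 8 of each list fell.

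Type I interferon response genes fell in 27 of 38 cases and rose in 5, with a median of -1.19, or -1.09 with undetected genes at their bounds (camera adjusted p = 0.000567, and adjusted p = 0.731 with an estimated correlation). BST2, which encodes the antiviral protein tetherin, fell at least 28.2-fold, and the ISG15 ligase gene HERC5 fell by 3.76 (SE 0.21). OAS1, which encodes an oligoadenylate synthetase, rose by 3.19 (SE 0.19), with other probes at 0.76 to 3.25, and the exonuclease gene ISG20 rose by 2.16 (SE 0.22). Adjusted over the list alone, 28 fell and 5 rose, and under median scaling 30 fell and 4 rose. The call was also lost with detection p under 0.01 on all 4 arrays (adjusted p = 0.0534).

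Of 17 genes of double-stranded RNA and nucleic acid sensing 9 fell and 3 rose, also adjusted over the list alone, with a median of -0.77. The DNA sensor AIM2 fell at least 10.5-fold, and STING1, an adaptor of cytosolic DNA sensing, was detected on 1 of 2 ADAR shRNA arrays and fell at least 5.76-fold. TRIM25 rose by 0.65 (SE 0.19) and TICAM1 by 0.64 (SE 0.21), but they read -0.020 and -0.0023 under median scaling, where 11 genes of the list fell and 0 rose. TRIM25 did not pass without scrambled replicate 1, scrambled replicate 2 or ADAR shRNA replicate 1 (0.63, 0.65 and 0.50, adjusted p = 0.0559, 0.0569 and 0.126), nor TICAM1 without scrambled replicate 1 or ADAR shRNA replicate 2 (0.50 and 0.45, adjusted p = 0.127 and 0.186) or with no filter on detection (adjusted p = 0.0526). Camera did not call the list (adjusted p = 0.118), but called it under median scaling (adjusted p = 0.0459) and with no normalization between arrays (adjusted p = 0.041). Of 19 NF-kB cytokines and targets 10 rose and 6 fell, or 11 and 6 adjusted over the list alone. The cytokine genes CXCL5 and IL6 rose by 4.05 (SE 0.45) and 3.64 (SE 0.20), while NFKBIA, an inhibitor of NF-kB, fell by 1.51 (SE 0.20) and CCL20 fell by 1.10 (SE 0.22). CXCL5, detected on 1 of 2 scrambled arrays, rose at least 16.5-fold against background, with another probe at 2.96, and rose by 4.77 without scrambled replicate 1 and 3.16 without scrambled replicate 2. Under median scaling 9 genes of the list rose and 8 fell. This list was not called either (adjusted p = 0.118), except under median scaling (adjusted p = 0.0373) and with no normalization (adjusted p = 0.0276). In MHC class I antigen presentation 5 of 17 genes rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.832). The chaperone gene CANX rose by 2.23 (SE 0.19) and HLA-F by 2.02 (SE 0.19), while the immunoproteasome genes PSMB8 and PSMB9 fell by 1.94 (SE 0.19) and fell by 1.57 (SE 0.25). Other probes read 0.88 for HLA-F, -1.88 to -0.40 for PSMB8 and -0.47 for PSMB9. For this list the median of -0.02 and the test's upward direction differed in sign, and 3 rose and 9 fell under median scaling.

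Of 30 genes of ATF4 and the integrated stress response 21 rose and 2 fell, with a median of 0.96 (camera adjusted p = 2.79e-05, and adjusted p = 0.731 with an estimated correlation). CTH, an enzyme of cysteine synthesis, rose by 3.40 (SE 0.19) and DDIT4 by 2.88 (SE 0.24). The amino acid transporter SLC7A5 fell by 0.98 (SE 0.27) and the serine synthesis gene PSPH fell by 0.82 (SE 0.26). SLC7A5 did not pass without scrambled replicate 2 or ADAR shRNA replicate 2 (-0.93 and -0.56, adjusted p = 0.0619 and 0.0938), nor PSPH without scrambled replicate 1 or ADAR shRNA replicate 2 (-0.46 and -0.67, adjusted p = 0.144 and 0.114) or with no filter on detection (adjusted p = 0.0757). Of 17 genes of the unfolded protein response of the endoplasmic reticulum 11 rose and 0 fell, with a median of 1.01 (camera adjusted p = 0.00103, and adjusted p = 0.731 with an estimated correlation). Its chaperone gene HSPA5 rose by 2.93 (SE 0.22) and PDIA6 by 1.77 (SE 0.25). Of 18 NRF2 oxidative stress genes 14 rose and 0 fell, or 15 and 0 adjusted over the list alone, with a median of 1.56 (camera adjusted p = 6.48e-06, and adjusted p = 0.731 with an estimated correlation). AKR1B10 and AKR1C2, which rose by 4.93 (SE 0.90), led it, and both varied between the scrambled arrays with SDs of 2.27 and 2.62 (n = 2). AKR1C2 rose by 6.86 without scrambled replicate 1 and 3.18 without scrambled replicate 2, and did not pass with a trend and robust variance (adjusted p = 0.136), and its other probes read 1.43 to 4.46. For the other lists of this paragraph the counts were equal adjusted over the list alone. Under median scaling 13 ATF4, 6 unfolded protein response and 11 NRF2 genes rose and 5, 1 and 0 fell; with no normalization between arrays 12, 4 and 11 rose and 5, 3 and 0 fell.

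Of 17 immediate early genes 12 rose and 2 fell, also adjusted over the list alone, with a median of 1.69 (camera adjusted p = 0.00058, and adjusted p = 0.731 with an estimated correlation). The phosphatase gene DUSP1 rose by 5.25 (SE 0.28) and the nuclear receptor gene NR4A2 by 3.05 (SE 0.25), while JUN fell by 2.21 (SE 0.20) and KLF6 fell by 0.88 (SE 0.19); under median scaling 11 rose and 4 fell. Of 21 p53 target genes 12 rose and 4 fell, also adjusted over the list alone, with a median of 0.77 (camera adjusted p = 0.0274, and adjusted p = 0.748 with an estimated correlation). GDF15, a secreted stress cytokine, rose by 4.41 (SE 0.19) and CDKN1A, an inhibitor of cyclin-dependent kinases, by 1.67 (SE 0.28). The polymerase gene POLH, detected on 1 of 2 ADAR shRNA arrays, fell at least 1.97-fold, with another probe at -0.52. ZMAT3 fell by 1.13 (SE 0.20), but 2 other ZMAT3 probes read 2.04 and 2.18. The p53 call was lost without ADAR shRNA replicate 1 (adjusted p = 0.0845) and with detection p under 0.01 on all 4 arrays (adjusted p = 0.121). Under median scaling 6 p53 target genes rose and 4 fell, and with no normalization between arrays 4 rose and 4 fell.

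Growth signalling, survival and metabolic lists were not called by camera. Of 22 genes of MAPK pathway output 8 rose and 10 fell, or 8 and 11 adjusted over the list alone (adjusted p = 0.701), including ETV4, which rose by 2.36 (SE 0.20), the receptor gene EPHA4, which rose by 2.22 (SE 0.22), EMP1, which fell by 5.33 (SE 0.19), and the feedback inhibitor SPRY1, which fell by 3.51 (SE 0.25). Of 20 apoptosis regulators 6 rose and 10 fell, or 6 and 11 adjusted over the list alone (adjusted p = 0.701). The survival gene BCL2 rose by 3.06 (SE 0.23), with other probes at 0.57 and 2.85. CASP9 rose by 1.43 (SE 0.24), with another probe at 0.66. The pro-apoptotic gene BIK fell at least 5.0002-fold. The survival gene BCL2L1 fell by 1.90 (SE 0.21), with another probe at -1.30. Of 29 hypoxia and glycolysis genes 7 rose and 9 fell, or 7 and 10 adjusted over the list alone (adjusted p = 0.832); the glucose transporter SLC2A3 rose by 4.39 (SE 0.34) and P4HA1 by 1.92 (SE 0.19), and PFKFB4 fell by 2.17 (SE 0.32) and EGLN3 fell by 1.97 (SE 0.21). SLC2A3 rose by 5.05 without scrambled replicate 1. Under median scaling 5 MAPK and 3 apoptosis genes rose and 14 and 12 fell, and of the hypoxia genes 3 rose and 14 fell under median scaling and with no normalization.

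Of 19 cholesterol synthesis genes 4 rose and 11 fell, also adjusted over the list alone (adjusted p = 0.219). SQLE and HMGCS1 fell by 1.87 (SE 0.19) and fell by 1.79 (SE 0.20), TM7SF2 rose by 0.79 (SE 0.26), and DHCR7 rose by 0.64 (SE 0.18) but read -0.073 under median scaling. Under median scaling 0 rose and 12 fell in this list, and with no normalization 0 rose and 14 fell. TM7SF2 read 0.18 (adjusted p = 0.527) and 0.051 (adjusted p = 0.868) there, and did not pass without scrambled replicate 1 (0.54, adjusted p = 0.153) or ADAR shRNA replicate 2 (0.50, adjusted p = 0.173), or with no filter on detection (adjusted p = 0.0792), nor DHCR7 without ADAR shRNA replicate 1 (0.58, adjusted p = 0.085). Of 14 fatty acid synthesis genes 4 rose and 3 fell, or 3 and 3 adjusted over the list alone (adjusted p = 0.532). ACSS2 rose by 1.61 (SE 0.20) and ACACA by 0.82 (SE 0.19), although ACACA read 0.12 (adjusted p = 0.637) under median scaling and -0.016 with no normalization between arrays, and FASN fell by 1.11 (SE 0.20) and ACLY fell by 0.66 (SE 0.21), which did not pass without scrambled replicate 2 or ADAR shRNA replicate 1 (-0.50 and -0.51, adjusted p = 0.1196 and 0.1425) or with the mean of all its probes (-0.42, adjusted p = 0.1008). The list's median of 0.24 was -0.37 under median scaling, where 1 rose and 5 fell. Among 31 transcripts with known A-to-I edited sites 7 rose and 11 fell, also adjusted over the list alone (adjusted p = 0.749). CYFIP2 rose by 3.91 (SE 0.18) and NOVA1 by 1.56 (SE 0.20), with another probe of each at 2.23 and 0.81. PAICS fell by 1.75 (SE 0.18), with other probes at -1.60 and 0.04. IGFBP7 fell by 1.45 (SE 0.31), or by 2.05 without ADAR shRNA replicate 1. Under median scaling 4 of these transcripts rose and 18 fell.

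Marker lists of lung epithelium and of other cell types moved in both directions and were not called by camera. All their counts were equal adjusted over the list alone. H358 is itself a lung line, so the alveolar and airway list does not mark other cells only. In the order below, 10 of 25, 7 of 21 and 5 of 15 listed markers entered the tests. Of 10 tested alveolar and airway genes 2 rose and 3 fell (adjusted p = 0.841); HOPX rose by 4.32 (SE 0.38) and the surfactant lipid transporter ABCA3 at least 5.77-fold, while the lung lineage factors FOXA2 and NKX2-1 fell at least 41.6-fold and at least 5.71-fold. The median of this list was 0.08, its mean -0.42 and its direction down, and the direction was up under median scaling. Another HOPX probe read 1.83, and HOPX rose by 3.69 without ADAR shRNA replicate 1 and 5.02 without ADAR shRNA replicate 2. Of 7 haematopoietic markers 2 rose and 3 fell (adjusted p = 0.749): CD14 by 4.01 (SE 0.27) and CD68 by 1.43 (SE 0.19) rose, with other CD68 probes at 0.30 and 1.08, and CORO1A and LAPTM5 fell at least 7.14-fold and at least 4.99-fold. Of 5 fibroblast and endothelial markers 2 rose and 2 fell (adjusted p = 0.996), with ENG up by 2.58 (SE 0.23), PDGFRB, detected on 1 of 2 scrambled arrays, up at least 2.06-fold, and LUM and COL1A1 down at least 3.48-fold and at least 1.61-fold. The median of that list was -0.41, with a mean of 0.06 and an upward test.

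Among 27 cytosolic ribosomal protein genes 6 rose and 1 fell (camera adjusted p = 0.286), but the list was called higher with cyclic loess (adjusted p = 0.0258), under median scaling (adjusted p = 0.000569) and with no normalization between arrays (adjusted p = 0.00203). RPS23 rose by 2.18 (SE 0.23) and RPL37 by 1.499 (SE 0.19), and RPL34 fell by 1.98 (SE 0.22). Of 23 oxidative phosphorylation genes 7 rose and 7 fell (adjusted p = 0.749), and the median of 0.13 was -0.35 under median scaling, where 1 rose and 8 fell; UQCRC2 rose by 2.73 (SE 0.19) and NDUFS1 by 0.82 (SE 0.21), and CYC1 fell by 1.60 (SE 0.22) and NDUFS3 fell by 0.87 (SE 0.20). NDUFS1 did not pass under median scaling (0.39, adjusted p = 0.111), with no normalization (0.25), or without scrambled replicate 1 or ADAR shRNA replicate 1 (0.66 for both, adjusted p = 0.0539 and 0.0663). Of 12 housekeeping controls 4 rose and 4 fell (adjusted p = 0.996): PPIA by 2.04 (SE 0.32) and GUSB by 1.43 (SE 0.19) rose, YWHAZ fell by 2.07 (SE 0.20), although another YWHAZ probe read -0.36, and ACTB, the gene of beta-actin, fell by 1.51 (SE 0.19); 2 rose and 5 fell under median scaling, and PPIA, detected on 1 of 2 scrambled arrays, rose at least 3.87-fold against background, or by 1.44 without scrambled replicate 2. The counts in these 3 lists were equal adjusted over the list alone. Camera called 9 of the 29 lists and, with an estimated correlation, called 0, with 1 list under an unadjusted p of 0.05. The estimate was -0.042 for immediate early genes, below the preset 0.01, so correlated members do not account for the loss of that call. For the other called lists it ran from 0.035 (S phase) to 0.547 (G2 and mitosis). In the simulation of 1 shifted list, camera with an estimated correlation also missed that list, which was shifted by 1 log2 unit. Its 0 calls therefore do not show that the lists were unchanged. Fry, which tests whether members move on balance one way, called 20.

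**Figure D2:**
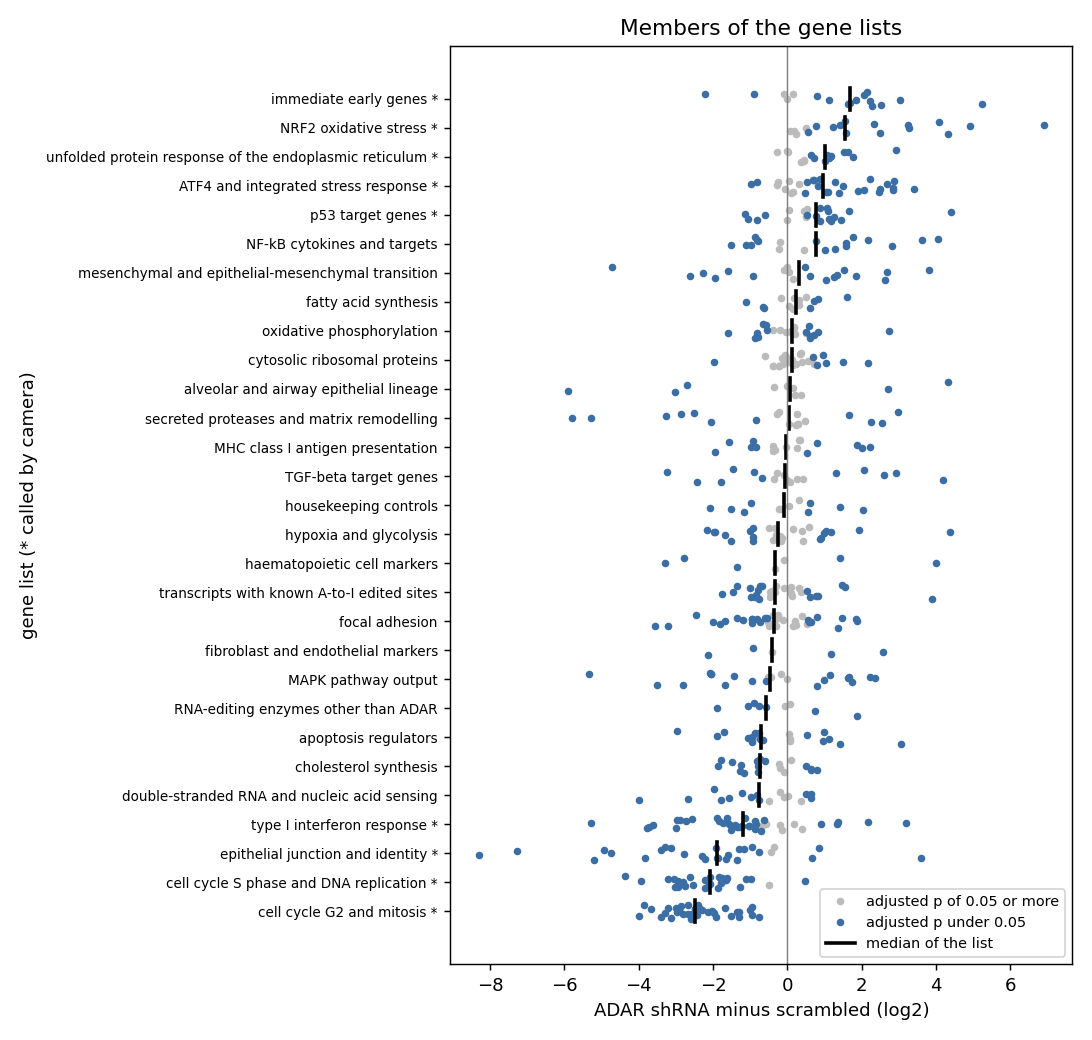
Log2 change (ADAR shRNA minus scrambled, horizontal axis) of each tested member of the 29 gene lists, with blue dots for adjusted p under 0.05, grey dots for the rest, black bars for list medians and an asterisk for the 9 lists called by camera. The medians run from -2.48 for G2 and mitosis to 1.69 for immediate early genes.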

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

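Probes without a gene name in the annotation used lay outside the comparison of genes, and many of them differed between the groups. Of 4995 such probes past the detection filter, 1869 differed between scrambled and ADAR shRNA cells at a limma adjusted p under 0.05, with 1078 higher and 791 lower in ADAR shRNA cells. Which transcripts they measure was not analysed here.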

How the results depend on the processing

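Background correction with no normalization between arrays was chosen after the data were seen. The count of risen genes moved from 3116 to 1730 under median scaling and 1375 with no normalization. That of fallen genes moved from 3928 to 6029 and 6426. It was 2533 with detection p under 0.01 on all 4 arrays, where fewer genes were tested. Median scaling equalized the medians over all 47322 probes, of which 39.6% to 44.2% were detected per array. The median of the tested genes was then -0.54, and -0.68 with no normalization, against -0.08 in the main fit. The risen and fallen counts moved with this shift of the median. Of the 29 lists camera called 9, and 6 with that filter and 0 with an estimated correlation, while fry called 20. Directions turned for TRIM25 (-0.020 under median scaling, -0.15 with no normalization), TICAM1 (-0.0023 and -0.14) and DHCR7 (-0.073 and -0.21). ACACA turned with no normalization (-0.016). The median of the tested genes was lower under these scalings, and no other cause was tested. ZMAT3 turned with the mean of all its probes (1.03), because its 2 other probes read 2.04 and 2.18. Leaving out a replicate gave 5848 to 6301 changed genes, 8 to 9 called lists and an ADAR change of -1.22 to -0.86, with the lone sample assumed to vary like the other group. The replicate numbers came from the titles. The series design names no pairing, so an unpaired fit was set in advance. Deviations of same-numbered arrays, computed afterwards, correlated at 0.106 over genes, with 2 pairs. With the replicate number as a block 7488 genes changed (3327 rose, 4161 fell), including all 7044. For named genes other than ADAR, 2122 comparisons with an alternative kept the side of the threshold, 56 lost the threshold and 8 turned. A change of sign was counted as kept where neither fit passed. Of 2476 second probes of changed genes, 260 had the opposite sign and 51 of these passed the threshold. Low signal over background limits genes undetected in a group to bounds.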

Other observations

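A further 10 gene families were chosen after values were seen. All 3 fibrinogen chain genes rose, FGG and FGA at least 170-fold and at least 32-fold and FGB, detected on 1 of 2 scrambled arrays, at least 4.52-fold, and all 5 measured type IV collagen genes rose, among them COL4A5 by 6.19 (SE 0.60) and COL4A6 by 5.89 (SE 0.36), each detected on 1 of 2 scrambled arrays and up at least 64.1-fold and at least 50.2-fold. Without scrambled replicate 1 and without scrambled replicate 2, COL4A5 rose by 7.29 and 5.02, and COL4A6 rose by 5.21 without scrambled replicate 2. Of 7 laminin genes 6 rose, including LAMC3 by 3.27, while LAMB3 fell by 2.87; under median scaling 4 rose and 1 fell, and LAMB1, LAMC1 and LAMA5 each lost the call with some replicate left out. LAMB1 and LAMC1 lost it without scrambled replicate 1 (0.49 and 0.47, adjusted p = 0.08705 and 0.0986), ADAR shRNA replicate 1 (0.71 and 0.60, adjusted p = 0.0601 and 0.0964) or ADAR shRNA replicate 2 (0.63 and 0.63, adjusted p = 0.085 and 0.0807), and LAMA5 without ADAR shRNA replicate 1 (0.62, adjusted p = 0.0749). The aldo-keto reductase genes AKR1C3 and AKR1C4 rose by 4.09 (SE 0.54) and 5.85 (SE 0.62), and 5 of 7 in that family rose, with 1 falling under no normalization and in the authors' values. Without scrambled replicate 1 and without scrambled replicate 2, AKR1C3 rose by 5.25 and 3.12, and AKR1C4 by 7.07 and 4.66. All 7 metallothionein genes fell, MT1E by 5.94 and MT1F at least 29.3-fold. Among 25 cancer-testis antigen genes 19 fell, and 17 of these were undetected in ADAR shRNA cells, among them MAGEA8, which fell at least 56.2-fold; MAGEA1 and MAGEB2 went the other way and rose by 3.45 and 2.50. Of 9 keratin genes 2 rose and 3 fell (2 and 5 under median scaling), of 13 claudins 3 rose and 5 fell (2 and 6), of 12 S100 genes 4 rose and 8 fell (3 and 8), and of 3 kallikrein-related genes 2 fell and 0 rose. In these families KRT9, CLDN14 and S100A11, and among the cancer-testis genes SSX3, lost the call without at least 1 replicate: KRT9 without scrambled replicate 1 (0.49), scrambled replicate 2 (0.63) or ADAR shRNA replicate 2 (0.53), CLDN14 without scrambled replicate 1 (0.52) or ADAR shRNA replicate 2 (0.53), S100A11 without scrambled replicate 2 (-0.45) or ADAR shRNA replicate 2 (-0.40), and SSX3 without scrambled replicate 1 (-0.68), scrambled replicate 2 (-0.55) or ADAR shRNA replicate 1 (-0.36). The directions of the fibrinogen, collagen and metallothionein families held under median scaling and with no normalization between arrays.

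The tests of a swapped sample, of fold gaps in raw signals and of a partial mixture were chosen after the size of the difference between the groups was seen. A swap of 1 array between the groups was argued against, since each array correlated with its own group better than with the other by at least 0.189; an exchange of both groups' labels would leave these correlations as they are, while ADAR was lower in the arrays labelled ADAR shRNA (-1.03, SE 0.21), as the labels say, although 2172 of 12197 genes lay as low or lower. Lower signal on the ADAR shRNA arrays was not excluded by the count set in advance, 3 probes undetected on both scrambled arrays with raw signal over 1000 on both ADAR shRNA arrays, where 10 were required, but was argued against as the whole cause by 108 probes at least 10-fold higher there without normalization. For cells of another type mixed into a group, 8 probes with raw signal over 5000 on both scrambled arrays were undetected on both ADAR shRNA arrays and 0 the other way, so the bound set in advance was not met; the later count, 329 probes at least 10-fold lower and 108 at least 10-fold higher, argues against an admixed share under 90% as the whole cause, and 83 genes also fell at least 16-fold after quantile normalization, but a smaller share beside a response of the cells themselves was not excluded. Groups holding cells of different origin or subclone may be a candidate explanation, which the tests did not decide. The medians of 232 windows of 50 neighbouring genes had an SD of 0.349, above the highest of 1000 shuffles of gene order (0.188). It stayed above with gene families reduced to 1 gene per symbol stem and chromosome (SD 0.351, highest shuffle 0.191). The bound set in advance for different origin, an SD above every shuffle in both forms, was therefore met. Medians of adjacent windows, not part of that bound, correlated at 0.602, against at most 0.223 in the shuffles. The shuffles treat neighbouring genes as independent, so neighbours that respond together would also exceed them, whatever the origin of the cells. Chromosome medians ran from -0.56 on chromosome 8 to 0.39 on chromosome 10. Of 7 genes with common null genotypes and a probe, 2 were detected on no array. Of the same 7 genes, 1 was present in 1 group and absent in the other, where 2 were required. A response of the cells to the loss of ADAR itself stays open and was not tested. The titles of both ADAR shRNA samples carry the letter B, which the labels do not explain. With this 1 ADAR shRNA group, loss of ADAR cannot be told apart from other effects of the shRNA given.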
